A study of Argopecten irradians concentricus with 9 samples.

How the data were processed

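RNA was taken from the adductor muscle, the muscle that closes the shell, of the bay scallop Argopecten irradians concentricus kept at room, high or low water temperature. Each temperature had 3 libraries, 9 in all. The labels give no temperature in degrees and no duration. They describe RNA isolated per tank, and do not say whether the 3 libraries of a group came from separate animals or tanks, so the p-values measure the spread between these libraries only.

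The submitters' processing notes name HISAT2 2.0.4 and HTSeq 0.9.1. The genome build, the settings and the strand setting are not given in the sources used here. The deposited table holds FPKM (fragments scaled by gene model length and library depth), per the file headers and file title, for 28864 gene models on numbered contigs, of which 2087 carry the file's own identifiers for models outside its main gene set. The table pairs 14302 gene models with a Swiss-Prot protein name and a further 3700 with a Pfam domain only. Names below are these best matches, so a name states similarity to a protein of another species. Contigs and coordinates are those of the table.

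The deposited FPKM multiplied by the gene length was a whole multiple of a fixed step in every library, with a largest distance from a whole number of 7.92e-09 read. The read numbers behind the values could therefore be read from the table: 11716140 to 16229040 assigned reads per library. The depth by which the authors divided was not this total. It was 13972000 reads times a median-of-ratios size factor in every library, so the deposited FPKM already carry a between-library scaling. No tool name for that scaling is given in the sources used here. Because the divisor differs from the total, FPKM sums differ between libraries.

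Tests were run with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with the pseudocount of 1, for the 8624 gene models with a mean FPKM of at least 1 over the 9 libraries. All 9 libraries entered a single fit with group means, moderated by eBayes with a trend. Genes were called at a Benjamini-Hochberg adjusted p under 0.05, with no fold threshold. A log2 change on this scale understates the change of genes of low FPKM. Gene lists, 29 fixed by words in the protein names before the data were examined, were tested with camera at a preset inter-gene correlation of 0.01, and again with an estimated correlation and with fry. Camera asks whether a list differs from the other genes. Fry, in the directional form given here, asks whether its members shifted in one direction, so their calls answer different questions. The form of fry for changes in either direction was not used for calls. The ribosomal pattern also took in S6 kinases and a ribosomal protein S19-binding protein. Lists with at least 5 tested members were used. They covered stress proteins, protein turnover, contraction, energy metabolism, translation, immunity, matrix and markers of other tissues.

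The genes named were chosen by a rule fixed before the data were examined. It takes, among called genes with a protein name and no overlap between groups, the 8 with the greatest rise and the 8 with the greatest fall. It adds the 2 called members of lowest adjusted p in each list. It adds the 3 most abundant members of the heat shock and contractile lists, whatever their result. It adds the 2 called genes of greatest change in each direction, whatever their annotation. Where fewer than 4 genes passed in a direction, the 4 of lowest p were taken. Called genes outside the rule are named as such.

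The scripts were tested on simulated data drawn with the real means and spread for low against room temperature, with 200 of 8624 genes changed. The 30 proteasome genes were lowered as well, and calls among them counted as true. The 200 genes were drawn from the more abundant ones. Genes were simulated independently, with the same spread in every library. The limma test recovered 2.99% of genes changed 2-fold, 74.6% of those changed 4-fold and 95.5% of those changed 8-fold, and 3.94% of its calls were false. So at 3 libraries per group a 2-fold change was mostly missed in this simulation.

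Alternatives fixed beforehand were a pseudocount of 0.1, no filter, a minimum mean FPKM of 5, 3 other scalings, a fit of only the groups compared, robust variance, array weights, a replicate block, a log2 threshold of 1 and leaving out each library. Added after seeing the data were voom on the recovered reads, voom with quality weights on the recovered reads, a fit without high temperature replicate 3 and low temperature replicate 3 together, and the estimated correlation joined to the other settings. Agreement between the high and low responses was set beside 100 simulations with no effect. Figures were drawn with matplotlib 3.10.9.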

Results

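RNA sequencing of bay scallop adductor muscle compared high and low water temperature with room temperature, with 3 libraries per group. Assigned reads ranged from 11716140 to 16229040 per library. The 50 most abundant gene models took from 50.28% of reads (high temperature replicate 1) to 62.51% (high temperature replicate 3). Libraries of a group correlated at r = 0.927 to 0.96 across genes, and libraries of different groups at 0.904 to 0.949. High temperature replicate 3 lay at 52 on the leading principal component, where the other 8 libraries lay between -28.5 and 13.8, and low temperature replicate 3 lay at -42.9 on the next.

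**Figure D1:**
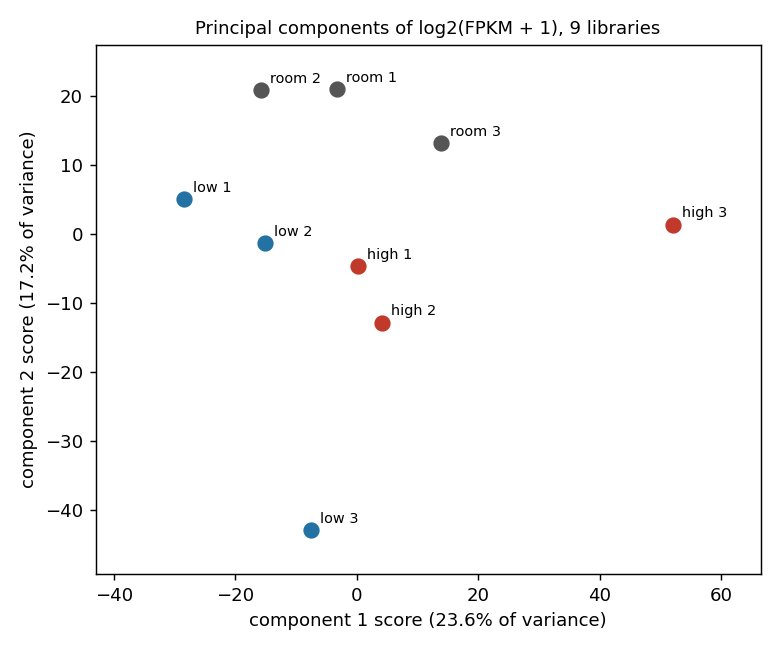
Principal component scores of log2(FPKM + 1) for the 9 libraries, a point per library, coloured by temperature group. High temperature replicate 3 (component 1 score 52) and low temperature replicate 3 (component 2 score -42.9) stand away from the rest.

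The comparison of low with room temperature asked which muscle genes respond to cold water. At low temperature 2 HSP70 gene models and those for DnaJ homolog subfamily B member 4, C/EBP gamma and alternative oxidase fell. The HSP70 gene matching major heat shock 70 kDa protein Ab, a chaperone that binds unfolded proteins, fell from 9.95 ± 2.62 FPKM at room temperature to 0.775 ± 0.596 at low temperature (SD, n = 3 each). Its log2 change was -2.66 (SE 0.334, limma adjusted p = 0.0131). DnaJ homolog subfamily B member 4, a co-chaperone of HSP70, fell from 34.7 ± 5.29 to 10.4 ± 1.49 FPKM (limma adjusted p = 0.0276). CCAAT/enhancer-binding protein gamma, a transcription factor, fell from 27.7 ± 3 to 4.80 ± 0.812 FPKM, a log2 change of -2.31 (SE 0.253, limma adjusted p = 0.00902).

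In all, 13 gene models were called lower at low temperature and 0 higher by limma. At an unadjusted p under 0.05 there were 415 lower and 289 higher. Voom on the recovered reads called 7 lower and 1 higher, and with quality weights 31 lower and 7 higher. In each of the 13 the groups did not overlap, which held for 15.3% of all tested genes where chance gives 10%. The match to growth/differentiation factor 15, a secreted factor of the TGF-beta family, had 1150 reads over the room temperature libraries and 3 over the low temperature libraries, a ratio of 359 (95% counting interval 123 to 1740, which covers counting error only). Alternative oxidase, a mitochondrial enzyme that passes electrons from ubiquinol to oxygen, fell from 5.22 ± 0.79 to 0.75 ± 0.1 FPKM (log2 change -1.82, limma adjusted p = 0.0165). Another HSP70 gene model, evm.TU.Contig769.20 on Contig769 from 396686 to 397642, fell by 2.25 on the log2 scale (limma adjusted p = 0.0422). It lies beside the Ab match, evm.TU.Contig769.21, which runs from 397960 to 398634 on the same strand, so reads of these similar models may not be separable. Whether the 2 models are parts of 1 gene was not tested. The ADAM protease match mig-17 fell by 1.91 (limma adjusted p = 0.0131). On the log2(FPKM + 1) scale, which compresses low values, the greatest falls were in gene models with no annotation, evm.TU.Contig257.11 (-5.60) and evm.TU.Contig179.11 (-3.75). Outside the naming rule, and chosen after their values were seen, a Noggin-domain gene, a bZIP transcription factor (evm.TU.Contig782.15) and the unannotated evm.TU.Contig826.22 and evm.TU.Contig965.9 were also called.

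**Figure D2:**
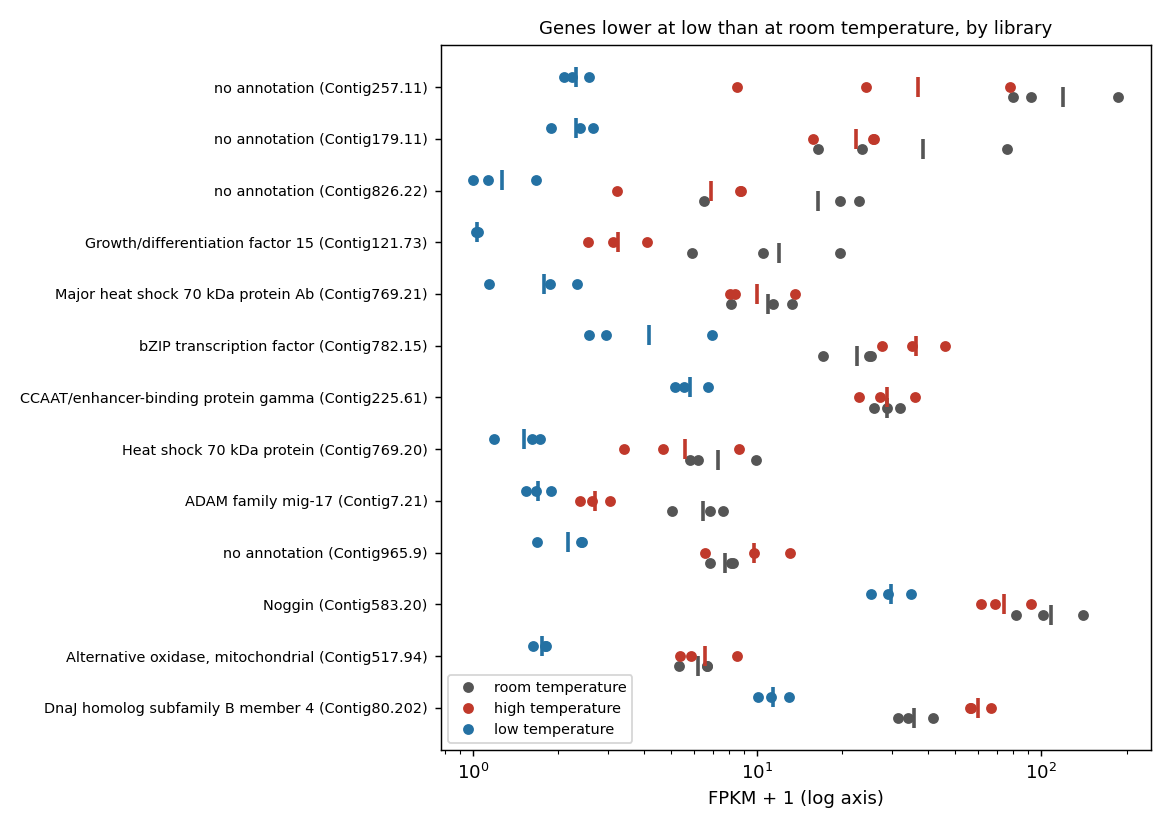
FPKM + 1 on a log axis for the 13 gene models called lower at low than at room temperature, a point per library and a vertical mark at the mean of each group of 3. The low temperature points lie below all room temperature points in each gene; growth/differentiation factor 15 falls from 11 to 0.0332 FPKM.

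These calls rested on few libraries. Of the 13 genes, 0 were still called without low temperature replicate 1, 5 without replicate 2 and 0 without replicate 3, 4, 7 and 6 without room temperature replicates 1, 2 and 3, and 0 with no filter on low values. Over the alternative settings, C/EBP gamma lost its call in 3 of 23 and the HSP70 Ab match in 7 of 23. Alternative oxidase lost it in 10 of 22, DnaJ homolog subfamily B member 4 in 13 of 23 and the HSP70 model evm.TU.Contig769.20 in 14 of 22. The 4 genes with the lowest p among those higher at low temperature did not pass: matches to zinc finger protein ush (log2 change 1.26, limma adjusted p = 0.0943), a DOMON-domain gene (1.67, 0.109), a leucine-rich repeat gene (1.17, 0.16) and the unannotated evm.TU.Contig479.56 (1.70, 0.0989).

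Among gene lists at low temperature, 6 of 29 were called by camera, all in the lower direction. Of 79 heat shock and co-chaperone genes, 3 fell and 0 rose over all genes tested, and 7 fell when adjusted over the list alone (median -0.321, camera adjusted p = 9.34e-07). With an estimated correlation its adjusted p = 0.352, and the fry adjusted p = 0.0356. The 30 proteasome subunits, which degrade ubiquitin-tagged proteins, had 26 members below 0 and a median of -0.46, with none called alone (camera adjusted p = 4.74e-06, adjusted p = 0.576 with an estimated correlation). For 63 mitochondrial ribosomal proteins the median was -0.282 (camera adjusted p = 0.000256, adjusted p = 0.727 with an estimated correlation). All 8 genes of the hypoxia response list lay below 0, of which alternative oxidase fell (camera adjusted p = 0.00152, adjusted p = 0.25 with an estimated correlation, fry adjusted p = 0.0356). Endoplasmic reticulum stress genes (0.0218, adjusted p = 0.727 with an estimated correlation) and translation factors (0.0355, adjusted p = 0.752 with an estimated correlation) completed the calls. So none of the 6 held with an estimated correlation. By fry, heat shock and hypoxia response genes passed. Proteasome subunits (fry adjusted p = 0.218), mitochondrial ribosomal proteins (0.577), endoplasmic reticulum stress genes (0.577) and translation factors (0.584) did not. Heat shock and proteasome genes were called under all 14 settings in which lists were tested. All 14 kept the preset correlation of 0.01, where the estimates were 0.0656 and 0.273. Other splits of the 6 libraries called up to 9 lists, and 3 of 10 splits, the real one included, gave at least 6. The number of called lists therefore did not set the real grouping apart. Hypoxia response genes lost the call with no filter on low values (adjusted p = 0.0715) and mitochondrial ribosomal proteins without low temperature replicate 1 (adjusted p = 0.1). In addition, endoplasmic reticulum stress genes were called in 10 of 14 (highest adjusted p = 0.216, without room temperature replicate 2) and translation factors in 9 of 14 (0.314, without low temperature replicate 1). Of 17 cilia marker genes, which mark gill and mantle epithelium, 12 lay below 0 (camera adjusted p = 0.0667, fry adjusted p = 0.0133). Markers of the digestive gland, gonad, nerve and shell or mantle had camera adjusted p of 0.423, 0.528, 0.696 and 0.481.

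**Figure D3:**
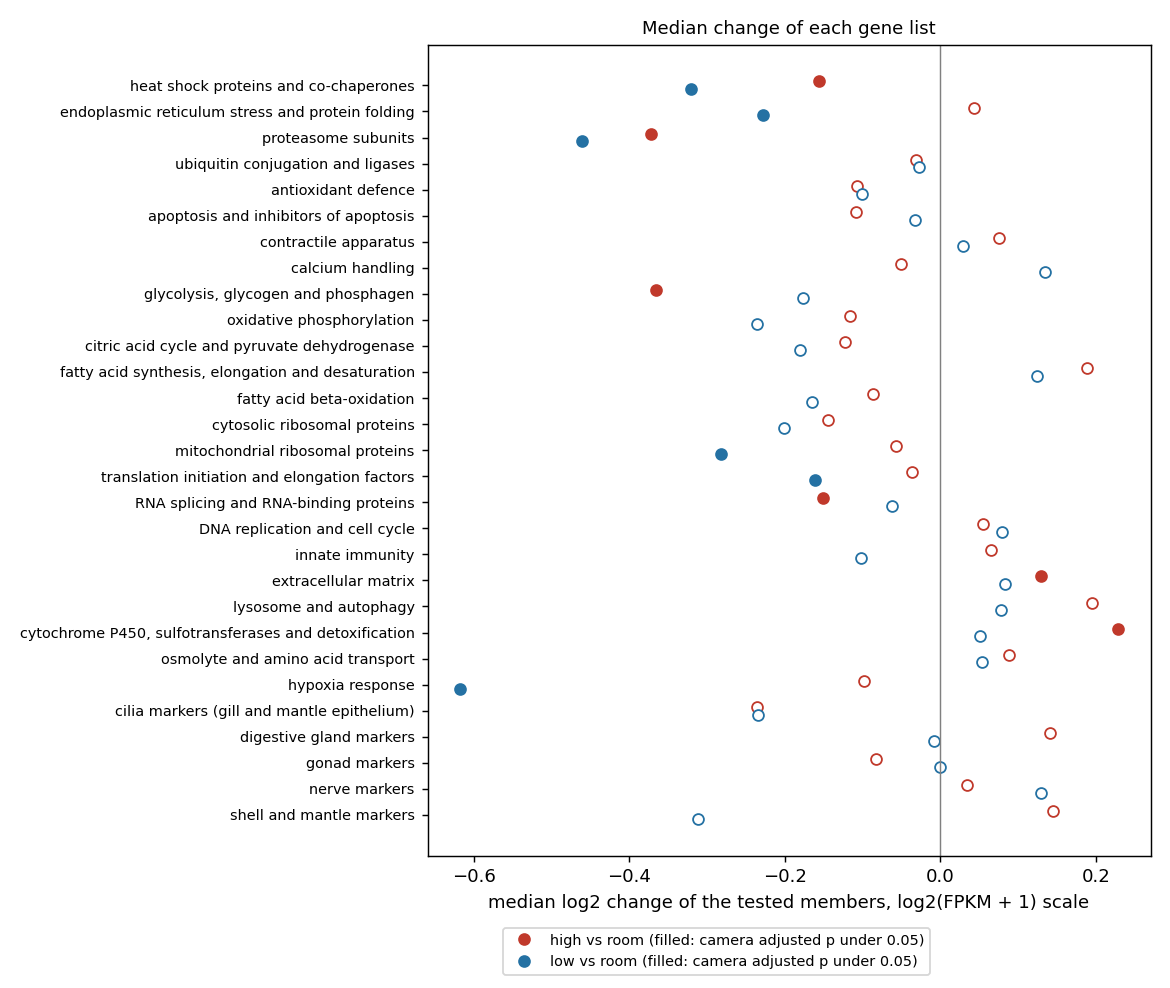
Median log2 change of the tested members of each of the 29 gene lists, on the log2(FPKM + 1) scale, at high (red) and low (blue) against room temperature. Filled points passed camera with a preset correlation; proteasome subunits lie at -0.372 and -0.46.

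The most abundant stress and contractile genes did not pass the test at low temperature. Alpha-crystallin B chain, a small heat shock protein, was at 4558 ± 2370 FPKM at room and 4044 ± 1040 at low temperature (limma adjusted p = 0.993). Heat shock protein beta-8 and DnaJ homolog subfamily B member 5 had log2 changes of 0.0469 and 0.106. Myosin regulatory light chain A was at 43170 ± 3400 and 41210 ± 12000 FPKM, adductor muscle actin at 23750 ± 4710 and 24260 ± 9300, and myosin essential light chain at 15700 ± 1640 and 16360 ± 5460. The 48 contractile genes had a median of 0.0297 (camera adjusted p = 0.528).

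The comparison of high with room temperature asked which muscle genes respond to warm water. No gene passed: limma called 0 higher and 0 lower, with 405 higher and 420 lower at an unadjusted p under 0.05. Voom on the recovered reads, with and without quality weights, also called 0. The lowest adjusted p was 0.293. Matches to matrix metalloproteinase-20, a protease of the extracellular matrix, were at 1.61 ± 0.326 FPKM at room and 8.12 ± 2.2 at high temperature (SD, n = 3), and to phosphoserine aminotransferase, an enzyme of serine synthesis, at 16 ± 7.38 and 70.8 ± 26.6. A bZIP gene (evm.TU.Contig79.116) and evm.TU.Contig479.56 followed, at log2 changes of 1.81 and 1.74. In the lower direction the lowest p belonged to a transmembrane protein match, evm.TU.Contig678.25 (-1.51), ADAM mig-17 (-1.26), FUN14 domain-containing protein 1, a mitochondrial outer membrane protein (-1.43), and an exocyst complex component 4 match on Contig423 (-1.07).

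Camera called 6 lists at high temperature. Proteasome subunits had 29 of 30 members below 0 and a median of -0.372 (camera adjusted p = 2.77e-05, adjusted p = 0.707 with an estimated correlation). Glycolysis, glycogen and phosphagen genes had a median of -0.366 (0.0139, adjusted p = 0.707 with an estimated correlation), RNA splicing genes -0.151 (0.0249, adjusted p = 0.707 with an estimated correlation) and heat shock genes -0.156 (0.043, adjusted p = 0.776 with an estimated correlation). In the higher direction were extracellular matrix genes (0.0448, adjusted p = 0.925 with an estimated correlation) and cytochrome P450 and detoxification genes (0.0476, adjusted p = 0.463 with an estimated correlation). Adjusted over the list alone, 1 matrix gene, matrix metalloproteinase-20, and 1 cytochrome P450 gene passed, against 0 over all genes. By fry none of the 6 passed: proteasome 0.263, glycolysis 0.325, RNA splicing 0.281, heat shock 0.325, matrix 0.823 and detoxification 0.0971 (fry adjusted p). Cilia markers, not called by camera, had a median of -0.236 (camera adjusted p = 0.111, fry adjusted p = 0.0283). Over the 14 settings the proteasome list was called in all 14, glycolysis and RNA splicing in 12 each, heat shock and matrix in 7 each and detoxification in 5 (highest adjusted p = 0.215). All 14 kept the preset correlation. Other splits of the 6 libraries called up to 10 lists, and 5 of 10 splits, the real one included, gave at least 6. The proteasome calls at high and at low temperature share the same room temperature libraries, so they are not independent. Between high and low temperature the proteasome list had a median of 0.0755 (camera adjusted p = 0.992). The number of called lists was 1 without room temperature replicate 2, 3 without high temperature replicate 1 and 3 without low temperature replicate 3. Without high temperature replicate 3, the library that stands apart, it was 9, of which 3 were among the 6: heat shock, matrix and detoxification genes were lost, and cytosolic ribosomal proteins (adjusted p = 6.68e-10), mitochondrial ribosomal proteins (0.000217), oxidative phosphorylation (0.000127), citric acid cycle (0.00498) and translation factors (0.0135) in the lower and lysosome genes (0.00498) in the higher direction were gained. With an estimated correlation 0 of the 9 passed, the lowest adjusted p = 0.518. The abundant genes did not pass: alpha-crystallin B was at 2997 ± 810 FPKM, heat shock protein beta-8 at 170 ± 35.1, DnaJ homolog subfamily B member 5 at 270 ± 97.8, myosin regulatory light chain A at 46880 ± 27600, adductor muscle actin at 25290 ± 18200 and myosin essential light chain at 18640 ± 8910.

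High and low temperature were also compared directly. EGR-1, DnaJ homolog subfamily B member 4, gene models for 2 HSP70 proteins and sequestosome-1 were among the genes higher at high than at low temperature. None of them was called at high against room temperature, so the calls do not show a rise with heat. Early growth response protein 1, a transcription factor, was at 8.44 ± 1.47 FPKM at high and 0.617 ± 0.34 at low temperature, a log2 difference of 2.56 (SE 0.274, limma adjusted p = 0.0048). DnaJ homolog subfamily B member 4 was at 58.9 ± 5.77 and 10.4 ± 1.49 FPKM (limma adjusted p = 0.0048), and the heat shock protein 70 B2 match evm.TU.Contig80.193 at 7.07 ± 4.51 and 0.527 ± 0.269 (limma adjusted p = 0.0383). The 3 other tested gene models of that name did not pass (limma adjusted p = 0.0853, 0.406 and 0.664). Sequestosome-1, an autophagy receptor, was at 99.3 ± 17.8 and 32.5 ± 4.29 FPKM (limma adjusted p = 0.0404).

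In total 13 gene models were higher and 1 lower at high than at low temperature by limma, with 554 and 470 at an unadjusted p under 0.05. Of the 13 higher, 7 were also called lower at low than at room temperature, and 0 were called at high against room temperature. Their median log2 change over all 13 was -1.82 for low minus room and 0.439 for high minus room. The others higher at high than at low temperature were Nup155, a nuclear pore protein (2.88), the HSP70 Ab match (2.51), C/EBP gamma (2.29), alternative oxidase (1.88), neuropeptide FF receptor 2 (1.47, limma adjusted p just under 0.05), evm.TU.Contig179.11 (3.26) and the bZIP gene evm.TU.Contig782.15 (3.24). A further bZIP gene (evm.TU.Contig79.116, 3.02) and evm.TU.Contig965.9 (2.14) were outside the naming rule. The gene lower at high temperature was a CECR6/TMEM121 family member (-3.61, limma adjusted p = 0.0151). Magnesium-dependent phosphatase 1 (-1.56), transmembrane protein 177 (-1.14) and frizzled-7 (-1.71) came next and did not pass. Of the 14 genes, 7, 6 and 5 were still called without low temperature replicates 1, 2 and 3, 8 without high temperature replicate 3, and 0 without high temperature replicate 3 and low temperature replicate 3 together, a fit chosen after seeing the data. Over the alternative settings, EGR-1 lost its call in 1 of 22 and DnaJ homolog subfamily B member 4 in 1 of 23. The HSP70 B2 match lost it in 10 of 22, sequestosome-1 in 14 of 23 and neuropeptide FF receptor 2 in 16 of 23.

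Of the heat shock list, 3 genes were higher at high than at low temperature over all genes, and 6 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.152). Endoplasmic reticulum stress genes were the called list (camera adjusted p = 0.0277, adjusted p = 0.95 with an estimated correlation, fry adjusted p = 0.411). The call held in 11 of 14 settings and was lost without high temperature replicate 2, without low temperature replicate 3 and without both libraries numbered 3 of the high and low groups (highest adjusted p = 0.377). In splits of the 6 high and low libraries, 10 of 10 called at least 1 list. Without high temperature replicate 3, 8 lists were called, of which 0 passed with an estimated correlation (lowest adjusted p = 0.909). Over the 14 settings, RNA splicing genes (camera adjusted p = 0.0616 with all libraries) passed in the lower direction in 5 and hypoxia response genes (0.0616) in the higher direction in 4. Cytosolic ribosomal proteins and oxidative phosphorylation genes each passed in the higher direction in 1, without high temperature replicate 1, and in the lower direction in 1, without high temperature replicate 3. None of these passed with an estimated correlation. In the endoplasmic reticulum stress list 0 passed over all genes and 5 adjusted over the list alone, among them 78 kDa glucose-regulated protein, a chaperone of the endoplasmic reticulum (1.85). The most abundant stress and contractile genes did not pass between high and low temperature, among them heat shock protein beta-8 (-0.85) and alpha-crystallin B (-0.43).

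With 0 genes called in high against room temperature, no overlap of called genes could be counted. The log2 changes at high and low temperature against the same 3 room temperature libraries correlated at 0.405 across 8624 genes, which are not independent replicates. With no effect, 100 simulations with shared room temperature libraries gave a mean of 0.501 (0.466 to 0.534). The share of genes with the same sign was 63.6% against a simulated 66.7% (65.2% to 67.8%), so both lay below the simulated ranges. The covariance, 0.0863 against a simulated 0.0786 (0.0712 to 0.086), lay just above. The simulations drew genes independently, with the same spread in every library. In the data, genes within some lists were correlated (estimated at 0.742 for cytosolic ribosomal proteins). Libraries also differed in quality weight (0.375 for high temperature replicate 3). The simulated ranges therefore cannot decide whether these values differ from no effect. With 3 room temperature libraries the controls were too few to split, and part of the covariance difference of 0.00772 may come from them.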

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

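Alternatives on recovered reads, the fit without high temperature replicate 3 and low temperature replicate 3 together, and the estimated correlation joined to other settings were chosen after seeing the data. The 27 gene calls, counting a gene once per comparison, kept their direction in all 614 values under alternatives, of which 408 passed the threshold and 206 did not. The 33 uncalled results of named genes gave 745 values, of which 54 reversed and 14 passed. The cause was not tested for any change below.

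The labels do not say that equal numbers pair the libraries, and not every same-numbered pair deviated together, so they were not taken as paired: of 9 same-numbered pairs, 3 had deviations correlated over 0.1 (range -0.103 to 0.242), and 6 of 9 libraries correlated best with their own number, a hint from the data and not the design. With the replicate block, low vs room called 10 lower and 0 higher (8 of the 13 reported among them), high vs low 15 higher and 3 lower (reported 1; 11 of the 14 reported among them), and high vs room 0. The replicate block changed a single list call: cytosolic ribosomal proteins passed in low vs room (adjusted p = 0.00777, adjusted p = 0.736 with an estimated correlation).

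The named genes below are myosin regulatory light chain A (evm.TU.Contig1462.6), actin (evm.TU.Contig251.4), myosin essential light chain (evm.TU.Contig731.36), alpha-crystallin B (evm.TU.Contig124.136), DnaJ homolog subfamily B member 5 (evm.TU.Contig280.5), heat shock protein beta-8 (evm.TU.Contig325.41). Pseudocount 0.1 gave 20 for the F test (reported 13), 3 for gene lists past the threshold, high vs low (reported 1). No filter on low values gave 0 for genes lower, low vs room (reported 13), 4 for genes higher, high vs low (reported 13), 0 for genes lower, high vs low (reported 1), 2 for the F test (reported 13), 3 for gene lists past the threshold, high vs room (reported 6), 2 for gene lists past the threshold, high vs low (reported 1). Minimum mean FPKM 5 gave 8 for genes lower, low vs room (reported 13), 2 for genes lower, high vs low (reported 1). Rescaled to equal sums gave 7 for genes lower, low vs room (reported 13). It reversed evm.TU.Contig1462.6, high vs room (0.0595), evm.TU.Contig124.136, low vs room (0.0871), evm.TU.Contig1462.6, low vs room (0.000996), evm.TU.Contig251.4, low vs room (0.0658). Equal medians gave a reversed sign for evm.TU.Contig124.136, low vs room (0.00925). Quantile normalization gave 8 for genes lower, low vs room (reported 13), 2 for gene lists past the threshold, high vs low (reported 1). It reversed evm.TU.Contig124.136, low vs room (0.204). Array weights gave 4 for genes higher, low vs room (reported 0), 27 for genes lower, low vs room (reported 13), 66 for genes higher, high vs low (reported 13), 23 for genes lower, high vs low (reported 1), 65 for the F test (reported 13). It reversed evm.TU.Contig280.5, high vs room (-0.109), evm.TU.Contig731.36, high vs room (-0.0979), evm.TU.Contig124.136, low vs room (0.0296), evm.TU.Contig1462.6, low vs room (0.0822), evm.TU.Contig251.4, low vs room (0.086), evm.TU.Contig1462.6, high vs low (-0.389), evm.TU.Contig731.36, high vs low (-0.134). Voom on recovered reads gave 1 for genes higher, low vs room (reported 0), 7 for genes lower, low vs room (reported 13), 23 for the F test (reported 13). Voom with quality weights on recovered reads gave 7 for genes higher, low vs room (reported 0), 31 for genes lower, low vs room (reported 13), 122 for genes higher, high vs low (reported 13), 60 for genes lower, high vs low (reported 1), 107 for the F test (reported 13). It reversed evm.TU.Contig280.5, high vs room (-0.264), evm.TU.Contig731.36, high vs room (-0.0459), evm.TU.Contig1462.6, low vs room (0.125), evm.TU.Contig251.4, low vs room (0.169), evm.TU.Contig1462.6, high vs low (-0.459), evm.TU.Contig731.36, high vs low (-0.131). Without high temperature replicate 3 and low temperature replicate 3 together gave 2 for genes lower, low vs room (reported 13), 0 for genes higher, high vs low (reported 13), 0 for the F test (reported 13), 10 for gene lists past the threshold, low vs room (reported 6), 0 for gene lists past the threshold, high vs low (reported 1). It reversed evm.TU.Contig280.5, high vs room (-0.251), evm.TU.Contig731.36, high vs room (-0.214), evm.TU.Contig731.36, low vs room (-0.217), evm.TU.Contig1462.6, high vs low (-0.373). Estimated inter-gene correlation gave 0 for gene lists past the threshold, high vs room (reported 6), 0 for gene lists past the threshold, low vs room (reported 6), 0 for gene lists past the threshold, high vs low (reported 1). Directional fry, which tests a list against no change where camera tests it against the other genes, gave 1 for gene lists past the threshold, high vs room (reported 6), 3 for gene lists past the threshold, low vs room (reported 6), 0 for gene lists past the threshold, high vs low (reported 1). The high vs room list was cilia markers, so none of the 6 reported there was kept. The low vs room lists were heat shock, hypoxia response and cilia markers, of which cilia markers were not among the 6. Estimated inter-gene correlation joined to each of 14 other settings, highest count gave 0 for gene lists past the threshold, high vs room (reported 6), 0 for gene lists past the threshold, low vs room (reported 6), 0 for gene lists past the threshold, high vs low (reported 1). Leaving out each library in turn, the ranges were genes higher, high vs room from 0 to 2, genes lower, high vs room from 0 to 1, genes higher, low vs room from 0 to 1, genes lower, low vs room from 0 to 12, genes higher, high vs low from 5 to 17, genes lower, high vs low from 0 to 2, the F test from 0 to 19, gene lists past the threshold, high vs room from 1 to 9, gene lists past the threshold, low vs room from 4 to 9, gene lists past the threshold, high vs low from 0 to 8, overlap of the high and low responses from 0 to 2. For named genes that did not pass, the log2 changes ranged for evm.TU.Contig280.5, high vs room from -0.251 to 0.283, evm.TU.Contig1462.6, high vs room from -0.477 to 0.203, evm.TU.Contig251.4, high vs room from -0.671 to 0.25, evm.TU.Contig731.36, high vs room from -0.214 to 0.393, evm.TU.Contig124.136, low vs room from -0.577 to 0.301, evm.TU.Contig325.41, low vs room from -0.253 to 0.433, evm.TU.Contig1462.6, low vs room from -0.318 to 0.107, evm.TU.Contig251.4, low vs room from -0.24 to 0.336, evm.TU.Contig731.36, low vs room from -0.217 to 0.292, evm.TU.Contig280.5, high vs low from -0.356 to 0.178, evm.TU.Contig1462.6, high vs low from -0.372 to 0.308, evm.TU.Contig251.4, high vs low from -0.631 to 0.29, evm.TU.Contig731.36, high vs low from -0.219 to 0.388.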

Other observations

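The tests of the 4 gene classes and of the summed HSP70 reads, the voom fit with quality weights and the estimated correlation under other settings were chosen after the values were seen.

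The remaining gene lists did not pass at low temperature with all libraries. Of 95 cytosolic ribosomal proteins, 85 lay below 0 (median log2 change -0.201, camera adjusted p = 0.126), as did 31 of 39 oxidative phosphorylation genes (-0.235, camera adjusted p = 0.18) and 22 of 28 citric acid cycle genes (-0.181, camera adjusted p = 0.227). Under the 14 other settings in which lists were tested, the cytosolic ribosomal list passed in the lower direction in 7, oxidative phosphorylation in 3 and cilia markers in 2. In the higher direction matrix genes passed in 3, transporters in 3 and calcium handling in 1. With an estimated correlation none of these passed under any setting. Glycolysis genes had a camera adjusted p = 0.272 and fatty acid beta-oxidation genes 0.294. Calcium handling genes, which set the contraction of muscle, had 19 of 30 members above 0 (0.135, camera adjusted p = 0.126), and osmolyte and amino acid transporters 32 of 54 (camera adjusted p = 0.144). Antioxidant (0.375), ubiquitin ligase (0.896), apoptosis (0.696), fatty acid synthesis (0.229), RNA splicing (0.864), DNA replication (0.696), innate immunity (0.578), matrix (0.227), lysosome (0.504) and detoxification genes (0.4) did not pass with all libraries.

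At high temperature, lysosome and autophagy genes had 34 of 50 members above 0 and a camera adjusted p = 0.0541, and passed in 5 of 14 other settings, with an estimated correlation in none (lowest adjusted p = 0.518). Contractile genes (0.426), oxidative phosphorylation (0.573), citric acid cycle (0.633), cytosolic ribosomal proteins (0.426), mitochondrial ribosomal proteins (0.318), endoplasmic reticulum stress (0.509), translation factors (0.509), antioxidant genes (0.573), innate immunity (0.426) and hypoxia response (0.609) did not pass with all libraries. Without high temperature replicate 3 oxidative phosphorylation, citric acid cycle, translation factors and both ribosomal lists did, in the lower direction, as given with the high temperature results; with an estimated correlation none did (adjusted p = 0.518 to 0.603). Contractile genes passed in 1 setting, without room temperature replicate 3 (0.0325), and endoplasmic reticulum stress genes in 1, without high temperature replicate 1 (0.046), both in the higher direction and neither with an estimated correlation. Apoptosis (0.573), ubiquitin ligases (0.633), calcium handling (0.968), DNA replication (0.968), fatty acid synthesis (0.318), beta-oxidation (0.324) and transporters (0.426) passed in no setting. Markers of the digestive gland, gonad, nerve and shell or mantle had camera adjusted p of 0.426, 0.968, 0.968 and 0.633.

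Low temperature called genes lower only, 13 against 0. The authors' scaling is not the whole cause: with equal sums, equal medians or quantile normalization the highest share of calls in the higher direction was 0%, although equal sums gave 7 calls, 5 of them among the 13. A pseudocount of 0.1 also gave 0% higher. With quality weights 7 of the calls were higher, so the absence of higher calls may in part depend on how libraries are weighted. A response to temperature stays open as a hypothesis.

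No gene was called at high temperature with all libraries. Limma called 2 without high temperature replicate 2, 2 without room temperature replicate 1 and 1 without room temperature replicate 3. High temperature replicate 3 stands apart, and without it limma still called 0 genes in high against room temperature, although leaving out a library also costs calls elsewhere. Array weights, which gave that library 0.375, called 0 at high temperature and 4 higher and 27 lower in low against room temperature, so its spread is not the whole cause. A weighted voom fit with 0 calls had been seen before this test was written. Weak or variable changes remain possible, since in the simulated data 3 libraries per group mostly missed 2-fold changes.

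The HSP70 genes may have fallen because reads moved between near-identical copies. Of the 7 tested inducible-type gene models, 6 lay below 0 at low against room temperature and 2 were called. The labels inducible-type and cognate were given here, and induction in this scallop was not tested. Summed over the 7 tested inducible-type HSP70 genes, depth-scaled reads were 110 ± 43.6 at room and 37.1 ± 4.11 at low temperature (SD, n = 3 each), a log2 change of -1.50, with every low temperature library below every room temperature library (exact permutation p = 0.1, two-sided, the smallest that 3 against 3 can give). The 4 cognate HSP70 genes did not gain: the log2 difference of their sum was -0.237. Movement among the summed copies would leave their sum unchanged, so it does not account for the lower sum. Movement to HSP70 gene models that were not tested, and reads left unassigned, were not examined. At high temperature the sum of the 7 genes was 108 ± 30.4, a log2 change of 0.00849 from room temperature.

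Whether whole classes fall at low temperature was tested as a hypothesis for each class inspected by eye: an integrated stress response panel, an immediate-early panel, bZIP transcription factors and cytosolic aminoacyl-tRNA ligases. Of the 20 ligases, 18 are also in the stress panel. With all members, camera with an estimated correlation gave adjusted p over the 4 classes of 0.0178, 0.0178, 0.116 and 0.104. Called genes had prompted the panels, so these values do not test them. Without every gene called in any comparison, the adjusted p was 0.104, 0.0652, 0.89 and 0.104, so none of the 4 passed. Leaving out called genes takes away the members that changed most, and the ligase class, which lost none, was picked after its members' values were seen (18 of 20 below 0). All 4 hypotheses therefore stay open.

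In the 10 splits of 6 libraries no share under 0.05 can be reached. High against room temperature called 0 genes and other splits up to 2; with 0 calls all 10 of 10 splits give as many whatever the data, so this split decides nothing. Low against room called 13 and other splits up to 1, so 1 of 10 gave as many. High against low called 14 and other splits up to 1, again 1 of 10. For gene lists the real splits gave 6, 6 and 1 and other splits up to 10, 9 and 9, with 5, 3 and 10 of 10 splits giving as many. The number of called lists therefore did not set the real groupings apart. The F test over 3 temperatures called 13 genes, the highest other split called 9, and 1 of 100 splits gave as many. With the main settings, the other arrangements drawn therefore did not reach this count. The 100 splits were drawn at random and are not all the possible ones. The count itself was unstable. It fell to 2 with no filter, and to 0 without high temperature replicate 3 and low temperature replicate 3 together. Splitting libraries also cannot address differences between tanks.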
